A study of Mus musculus with 6 samples.

How the data were processed

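RNA was measured in 6 libraries of mouse embryonic stem cells, 3 wild type and 3 carrying a CRISPR/Cas9-made mutation of uORF1 of Atf4, an upstream open reading frame in the leader of its mRNA. Per the labels' protocols, RNA was purified with Trizol-LS and libraries were made with the TruSeq Stranded Total RNA kit, which keeps RNAs without a poly(A) tail and marks the strand. The deposited table holds whole-number read counts per gene symbol and library, not normalised, as its values show. HISAT2 2.0.4, HTSeq and the genome build mm10 are named per the submitters' processing notes, which give no roles, settings or order. The HTSeq strand setting, the treatment of reads that map to several places and the gene annotation are not given in the sources used here. Counts of genes that overlap, lie antisense to each other or have near-identical copies (such as histone genes, Zscan4d and Usp17le) are therefore uncertain.

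The table holds 24061 symbols, of which 5535 had no read in any library. Total counts per library ran from 14297150 to 21298804, so that 1 count was worth 0.0465 to 0.0713 CPM (counts scaled to a common library size, per 1e6). Rn45s, the 45S ribosomal RNA precursor, took 27.6% to 36.9% of the counts of a library and stayed in the library sizes. Columns were assigned to samples by their names, and each group was taken from the labels' genotype. Replicates were compared before use. Counts of every pair within a group differed by more than sampling noise (chi-square per degree of freedom 1.92 to 27.2), so each library counted as 1 replicate. Rn45s was among these counts. The lowest value was that of mutant replicates 1 and 3, whose Rn45s shares were 31.2% and 31.5%. The differences may therefore be technical and do not show that the libraries are biologically separate. Coordinates, transcript GC content and biotypes came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. Of the symbols, 22749 matched directly, 934 matched through a RefSeq synonym and 378 did not match. None of the 13 mitochondrially encoded gene symbols matched the table, so those genes were not analysed here.

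Differences between mutant and wild type were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust estimation, TMM scaling factors and the filterByExpr filter (minimum count 10), which left 13101 genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 fold changes are mutant over wild type, and their standard error (SE) was taken as the size of the fold change over the square root of the test's F. CPM are TMM-scaled, and errors beside means are SD over n = 3 libraries. Of the 26 gene lists, those with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 (correlation between genes preset at 0.01), adjusted over the lists. Camera was repeated with an estimated correlation. Fry, which tests the genes of a list on their own rather than against other genes, was run for direction. Single values per library were compared by exact permutation tests, two-sided, whose smallest p for 3 against 3 is 0.1.

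The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Atf4, the 8 largest rises and 8 largest falls among genes past the threshold with non-overlapping groups and a mean of at least 1 CPM (without symbols of Gm and a digit, Rik symbols or bare identifiers), the 4 members with the smallest p of each of the 4 ATF4 lists, 2 of each other list if at least 1 member passed, and in any case 2 Y-linked genes and the 2 most abundant naive pluripotency genes. Genes named beyond it were chosen after their values were seen.

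The alternatives named in advance were median-of-ratios size factors, library size only, upper quartile factors, a fit without robust estimation, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, leaving out each library, leaving out 211 symbols of ribosomal RNA, small RNA and histone genes, DESeq2 1.42.0, limma voom, an adjusted p under 0.01, and a fold change of at least 2. A GC correction, leaving out chromosomes 1, 6 and 8, both together, and leaving Meg3, Rian and Mirg out of the imprinted list were added after seeing the data. The GC correction entered a loess curve (span 0.3) of each library's log2 deviation on the GC content of the longest transcript as an offset. It used the 13013 genes (99.3% of those tested) with a GC value. Chromosomes were described in windows of 5 Mb, and the segment boundaries on chromosomes 1 and 6 were chosen after seeing the data. Intervals of medians are 95% bootstrap intervals from 2000 draws over genes. They treat genes as independent and do not cover the spread between libraries.

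The test was tried on counts simulated for the comparison of mutant with wild type (12994 genes tested). It recovered 42.0% of genes changed 1.25-fold, 70.0% of those changed 1.5-fold, 96.0% of those changed 2-fold and 100.0% of those changed 4-fold, with 10 false calls (6.13% of calls). The same straight-line GC trend was then added to all 3 mutant libraries (12970 genes tested). The uncorrected test made 2931 false calls (94.5% of calls), and the test with the GC correction made 10 (5.99% of calls, 12886 genes tested). In the real libraries the GC slope differed within a genotype (0.13 to 0.27 per 10 points in the mutant), so these shares need not hold for them. The share of false calls also depends on how many genes were changed, here 49 or 50 tested genes at each fold. No shift of a chromosome was simulated. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.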

Results

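Total RNA was sequenced from mouse embryonic stem cells (mESC), pluripotent cells of the early embryo that grow in culture, either wild type or mutated in uORF1 of Atf4. ATF4 is the main transcription factor of the integrated stress response (ISR), in which phosphorylation of eIF2 lowers general translation while upstream open reading frames (uORFs) in the Atf4 leader let ATF4 be translated. The series title concerns the plasticity of this response, and the design compares the mutant with the wild type; the labels name no stress treatment. Each genotype had 3 libraries. The labels do not say whether these came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical.

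The libraries held 14877217, 14710666 and 14297150 counts in wild type and 21298804, 16317340 and 17920626 in the mutant. Every mutant library was deeper than every wild-type library (exact permutation p = 0.1, the smallest possible for 3 against 3). The ribosomal RNA precursor Rn45s took 31.7% ± 4.72 of the counts in wild type and 33.2% ± 3.21 in the mutant (SD, n = 3, exact permutation p = 0.5). Log2 CPM correlated across genes with Pearson's r of 0.992 to 0.995 within a genotype and 0.965 to 0.975 between genotypes. The main axis of variation, with 75.0% of the variance, separated the genotypes.

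Atf4 mRNA was lower in the mutant. The gene lies on chromosome 15 (80255184 to 80257541, plus strand, mm10) and is protein coding. Its level was 34.3, 29.9 and 33.2 CPM in the wild-type libraries and 16.6, 20.02 and 17.7 CPM in the mutant libraries. The mean fell 1.80-fold, from 32.5 ± 2.28 to 18.1 ± 1.75 CPM (SD, n = 3, log2 fold change −0.85, SE 0.09, adjusted p = 1.32e-09). Counts per gene show neither the mutation itself nor how much ATF4 protein was made, and the position of the edit is not given in the sources used here.

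**Figure D1:**
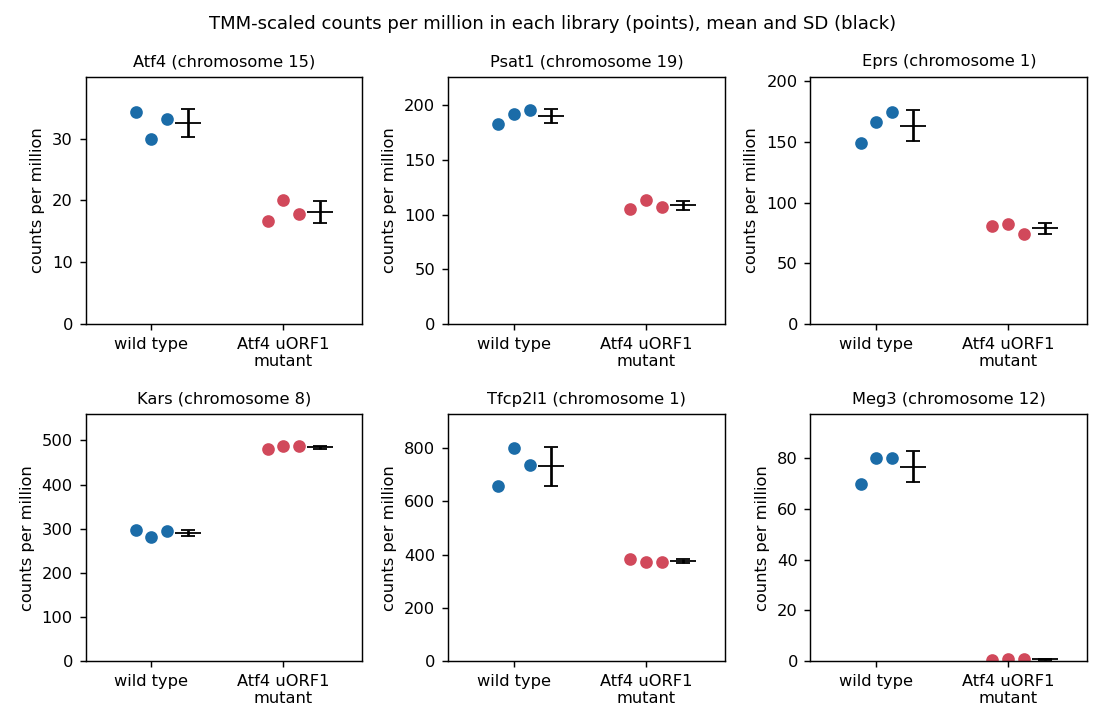
CPM of Atf4, Psat1, Eprs, Kars, Tfcp2l1 and Meg3 in each of the 3 wild-type and 3 mutant libraries (points), with mean and SD (bars). The groups do not overlap for any of the 6 genes, and Kars is the gene of the set that is higher in the mutant.

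The difference between the genotypes reached far beyond Atf4. Of 13101 tested genes, 3286 were higher and 3493 lower in the mutant (51.7% of those tested), 323 and 536 of them by 2-fold or more. The 2-fold counts were 267 and 299 with the GC correction, 133 and 458 without chromosomes 1, 6 and 8, and 103 and 256 with both. With library size only as the scaling, 1854 were higher and 3156 lower, so that the share of higher genes among the calls was 37.0% rather than 48.5%. The groups did not overlap for 57.8% of tested genes, where chance gives 10%. The spread between libraries of a genotype was small, with a biological coefficient of variation of 5.58%.

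Among genes with a mean of at least 1 CPM and not named by a bare identifier, the 8 largest rises included developmental and endothelial genes that stayed at low levels. Cdh5, the adhesion protein VE-cadherin of endothelial cells, rose from 0.373 ± 0.15 to 3.57 ± 0.608 CPM (log2 fold change 3.21, SE 0.30, adjusted p = 9.75e-11), and the endothelial receptor gene Tie1 rose by 2.01 on the log2 scale. Olig3, a transcription factor of the developing nervous system, rose by 2.15, and the homeobox genes Hoxa1 and Hoxa5 rose by 1.93 and 1.91. The others were Cadps2 (2.18), Fam131b (1.99) and Dppa3 (1.97), an oocyte and germ cell factor that also marks naive pluripotent cells. Cdh5 lies on chromosome 8, and Hoxa1, Hoxa5 and Fam131b lie between 40 and 95 Mb of chromosome 6, where most genes were higher. Genes antisense to the Hoxa genes are annotated, and the strand setting of the counting is not given, so these counts may include antisense reads.

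Within the same limits, the largest falls were of the noncoding RNAs Meg3, Mirg and Rian, which are normally made from the maternal copy of an imprinted domain on chromosome 12. Meg3 (109541001 to 109571726, lincRNA) fell 86.1-fold, from 76.5 ± 5.996 to 0.8998 ± 0.176 CPM (log2 fold change −6.43, SE 0.13, adjusted p = 5.78e-28). Rian (109603940 to 109661716) fell 50.6-fold, from 218 ± 12.4 to 4.26 ± 0.498 CPM, and Mirg (109729764 to 109749460) fell by 6.02 on the log2 scale. The microRNA genes Mir382 and Mir668, which lie within Mirg, held 132 and 99 counts over the wild-type libraries and 4 counts each over the mutant libraries. These counts may include reads of Mirg itself. Outside this domain, Neb, which encodes the giant muscle protein nebulin, fell by 3.44, the adhesion receptor gene Gpr126 by 3.00 and Dcdc2a by 2.72 on the log2 scale (all 3 past the threshold).

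The calls followed chromosomal position. On chromosome 8, 549 of 709 tested genes were higher and 31 lower, with a median log2 fold change of 0.58. Between 40 and 95 Mb of chromosome 6, 215 of 245 genes were higher and 5 lower, and beyond 55 Mb on chromosome 1, 361 of 580 were lower and 30 higher. Relative to the other autosomes and after the GC correction, the medians were 0.54 (95% interval 0.52 to 0.58), 0.89 (0.86 to 0.94) and −0.27 (−0.30 to −0.24). Each mutant library lay 0.55 to 0.56 above the wild-type mean on chromosome 8 (exact permutation p = 0.1, n = 3 per genotype). The rest of chromosome 6 had a median of 0.06 over 365 genes. The first 55 Mb of chromosome 1 stood at 0.18 over 145 genes after the GC correction and at −0.03 before it. Medians of the remaining autosomes lay between −0.14 and 0.06, and between −0.04 and 0.01 after the GC correction. Single windows of 5 Mb there could lie further out. After the GC correction, the window that starts at 175000001 on chromosome 2 stood at −0.81 (15 genes). The window that starts at 70000001 on chromosome 16 stood at 0.54 (3 genes).

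**Figure D2:**
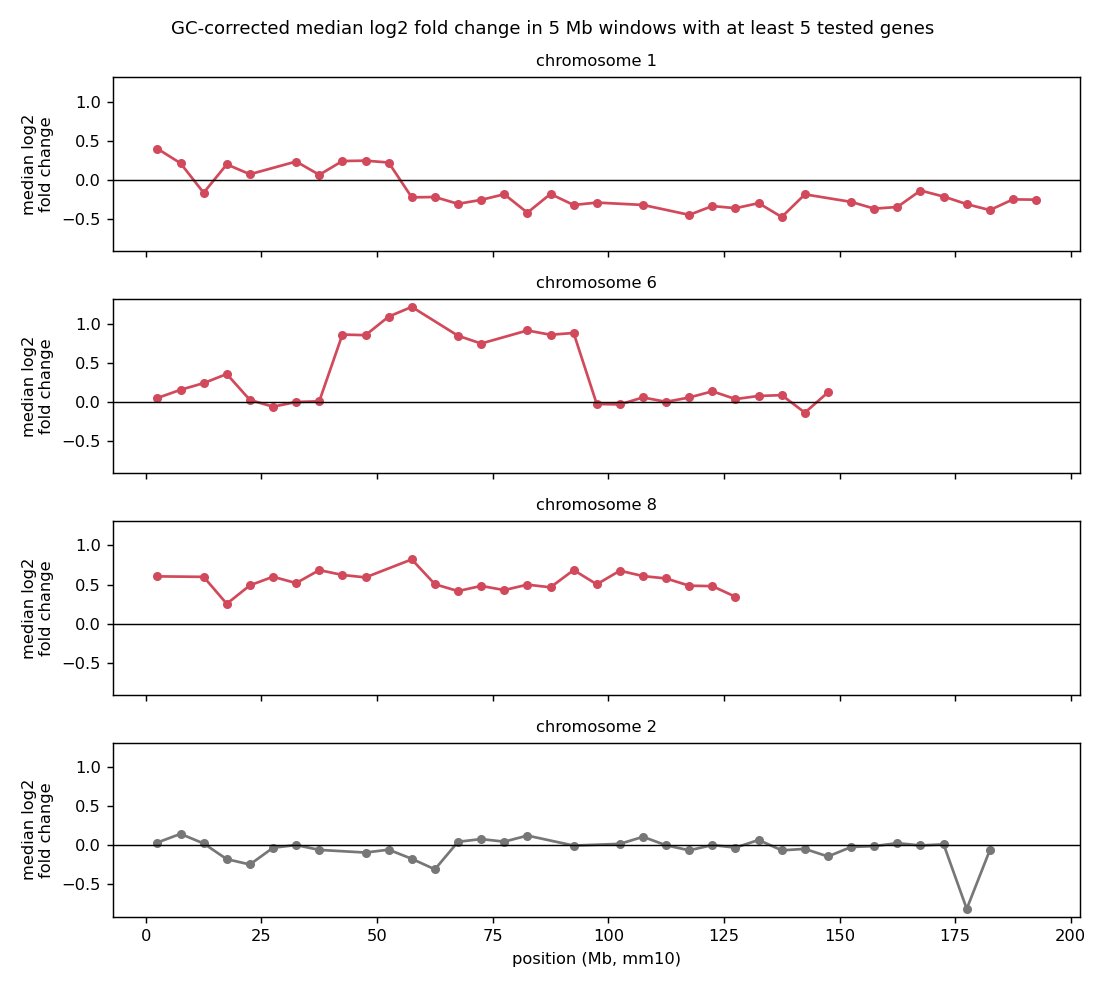
Median GC-corrected log2 fold change (mutant over wild type) of the tested genes in windows of 5 Mb (at least 5 genes each) against position in Mb on chromosomes 1, 6, 8 and 2. The 15 windows of chromosome 8 with at least 20 genes lie between 0.42 and 0.69, and the 9 windows from 40 to 95 Mb of chromosome 6 lie between 0.75 and 1.21. On chromosome 2, the window that starts at 175000001 lies at −0.81 (15 genes).

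The calls also followed the GC content of the transcripts. Across genes, GC content and log2 fold change had a Spearman correlation of 0.485 and a Pearson correlation of 0.421 (genes are not independent replicates). With genes in 10 bins of GC content, the lowest bin (29.1% to 41.6%) had a median log2 fold change of −0.54 and the highest (58.2% to 72.8%) had 0.23. The slope of a library's log2 deviation per 10 points of GC was −0.18 ± 0.08 in wild type and 0.18 ± 0.07 in the mutant (SD, n = 3, exact permutation p = 0.1). After the GC correction, 3010 genes were higher and 3083 lower; 4627 genes were called both with and without it, 4524 of them in the same direction. With chromosomes 1, 6 and 8 also left out, 2009 were higher and 2583 lower.

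**Figure D3:**
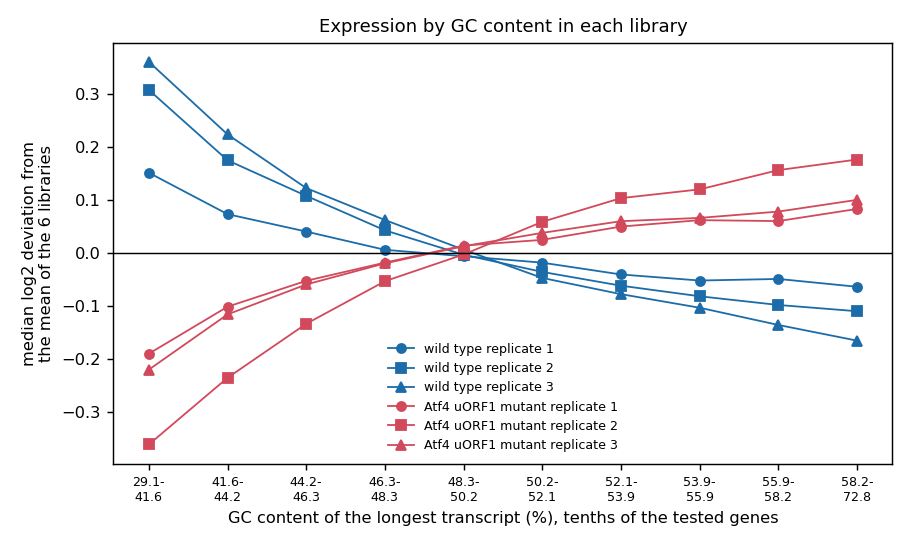
Median log2 deviation of each library from the mean of all 6, for genes in 10 bins of GC content. Wild-type and mutant libraries run in opposite directions, with 0.36 in the lowest bin for wild type replicate 3 and 0.18 in the highest bin for mutant replicate 2.

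The ATF4 programme was described with 4 lists. Of 15 tested enzymes of amino acid synthesis and one-carbon metabolism, 8 fell, 2 rose and 5 did not pass. Psat1, an aminotransferase of serine synthesis, fell from 190 ± 6.52 to 109 ± 4.06 CPM (log2 fold change −0.81, SE 0.06, adjusted p = 2.81e-13). Aldh18a1, which opens proline synthesis, fell by 0.68, and the asparagine synthetase gene Asns fell by 0.48 on the log2 scale. Got1, the cytosolic aspartate aminotransferase gene, rose by 0.42. The list median was −0.23, and the list was not separated from other genes (camera adjusted p = 0.124, range over alternatives 8.86e-04 to 0.483). The GC correction brought it past the threshold (adjusted p = 0.0206, and 8.86e-04 without chromosomes 1, 6 and 8 as well), which was lost again together with an estimated correlation (adjusted p = 0.457 and adjusted p = 0.150). Adjusted over the list alone, the counts were again 8 lower and 2 higher, and without wild type replicate 1, 4 were higher.

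Of 20 cytosolic aminoacyl-tRNA synthetase genes, whose enzymes load amino acids onto tRNAs, 11 fell and 7 rose, with the same counts adjusted over the list alone. The direction followed position. All 4 members on chromosome 8 or between 40 and 95 Mb of chromosome 6 rose, and of the other 16, 11 fell and 3 rose. With the GC correction, Aars (chromosome 8) stood at 0.12 (adjusted p = 0.0536) and no longer passed. The rises of Vars (−0.02, adjusted p = 0.799) and Wars (0.06, adjusted p = 0.422), which lie elsewhere, were lost too. Qars then passed as lower (−0.13, adjusted p = 0.0385). These 4 genes were named after their values were seen. Kars (lysine, chromosome 8) rose from 291 ± 7.59 to 484 ± 3.81 CPM, a log2 fold change of 0.74 (SE 0.05, adjusted p = 5.31e-13), and Farsa (phenylalanine, chromosome 8) rose by 0.82. Eprs (glutamate and proline) and Dars (aspartate), both beyond 55 Mb on chromosome 1, fell by 1.05 and 0.90. The fall of Dars was −0.47 with the GC correction. Elsewhere, Cars (cysteine, chromosome 7) fell by 0.93 and Iars (isoleucine, chromosome 13) by 0.59, both named after their values were seen. The list median was −0.28 (camera adjusted p = 0.172, range over alternatives 2.72e-04 to 0.672). Without chromosomes 1, 6 and 8 the adjusted p was 0.0369, and with the GC correction as well 2.72e-04; with an estimated correlation on top, the adjusted p was 0.338.

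**Figure D4:**
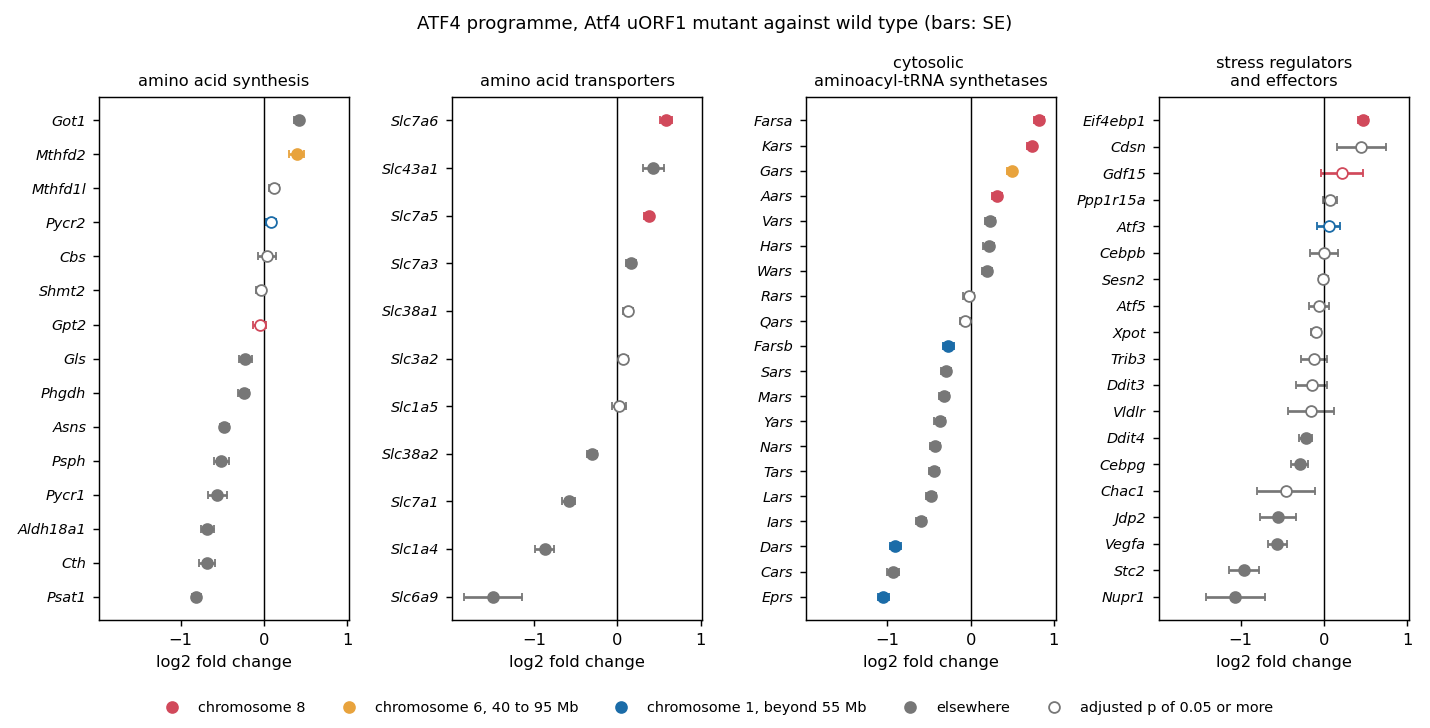
Log2 fold change (mutant over wild type, bars SE) of each tested member of the 4 ATF4 lists, coloured by chromosomal place, with open symbols for an adjusted p of 0.05 or more. All 4 aminoacyl-tRNA synthetase genes on chromosome 8 or between 40 and 95 Mb of chromosome 6 lie above 0, and 11 of the other 16 passed the threshold below 0.

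Of 11 tested amino acid transporters, 4 rose and 4 fell (5 and 4 adjusted over the list alone). Slc1a4, a neutral amino acid transporter, fell from 13.7 ± 0.293 to 7.59 ± 1.11 CPM (log2 fold change −0.87, SE 0.11, adjusted p = 1.19e-07), and Slc7a1, a transporter of cationic amino acids, fell by 0.58. Slc7a6 and Slc7a5, light chains of amino acid exchangers and both on chromosome 8, rose by 0.59 and 0.38; with the GC correction the rise of Slc7a5 was 0.19. The median of the list was 0.07, the mean was −0.13 and camera pointed up (adjusted p = 0.968); with library size only, without chromosomes 1, 6 and 8, or with the GC correction (median −0.07), camera pointed down. The cystine transporter gene Slc7a11, a known ATF4 target, had at most 2 counts in a library and was not testable at this depth (named after its counts were seen).

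Of 19 tested stress regulators and effectors downstream of ATF4, 6 fell and 1 rose, with the same counts adjusted over the list alone. DESeq2 called 3 lower and 1 higher, and the lower count was also 3 without wild type replicate 3. Stc2, which encodes a secreted glycoprotein, fell from 4.41 ± 0.428 to 2.27 ± 0.158 CPM (log2 fold change −0.96, SE 0.18, adjusted p = 3.11e-05), and the growth factor gene Vegfa fell by 0.56. Eif4ebp1, the gene of a translation repressor on chromosome 8, rose by 0.47. Nupr1, a stress-induced chromatin protein, fell from 1.20 ± 0.384 to 0.590 ± 0.235 CPM (adjusted p = 0.0120). That call was lost without wild type replicate 3 (adjusted p = 0.0918), without mutant replicate 1 (0.110) and with DESeq2 (0.0568), over a range of 0.00609 to 0.110. Ddit3, which encodes CHOP, had a log2 fold change of −0.15 (adjusted p = 0.527), and Trib3 had −0.12 (adjusted p = 0.549), both named after their values were seen; with the GC correction they stood at 0.00 (adjusted p = 0.985) and −0.33 (adjusted p = 0.0674). Over the list the median was −0.12 (−0.27 to −0.07 over alternatives; camera adjusted p = 0.668). Fgf21, named after its counts were seen, had no count in any library.

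In the ISR machinery itself, the list of eIF2 kinases, eIF2 and eIF2B subunits and related factors, 7 of 17 genes fell and 2 rose, with the same counts adjusted over the list alone (median −0.08, camera adjusted p = 0.140). Eif2s2, the beta subunit of eIF2, fell from 91.9 ± 8.91 to 35.0 ± 4.12 CPM (log2 fold change −1.39, SE 0.08, adjusted p = 6.46e-15). It has a transcript GC content of 38.7%, and its fall with the GC correction was −0.81. Ppp1r15b, the constitutive regulatory subunit of the eIF2 phosphatase, fell by 0.57 and lies beyond 55 Mb on chromosome 1. The kinase gene Eif2ak3 (PERK), on chromosome 6 and named after its values were seen, rose by 0.72. After the GC correction, 6 members were lower and 3 higher and the median was −0.01, and without chromosomes 1, 6 and 8 as well it was 0.00, with camera pointing down in both; with library size only it was −0.15.

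Among the other stress pathways, the NRF2 targets, genes of the oxidative stress response, passed the list test as higher (camera adjusted p = 0.0321), but not with an estimated correlation (adjusted p = 0.483 with an estimated correlation). Of 14 tested, 8 rose and 0 fell by edgeR, with the same counts adjusted over the list alone, at an unadjusted p under 0.05, by DESeq2 and by limma voom. Hmox1, the heme oxygenase gene, rose from 40.5 ± 1.37 to 86.9 ± 2.04 CPM (log2 fold change 1.10, SE 0.07, adjusted p = 5.94e-15), and the glutathione reductase gene Gsr rose by 0.59. Both lie on chromosome 8, as does Nqo1 (1.01, named after its values were seen), and 5 of the 11 members elsewhere also rose. The median was 0.19 (0.10 to 0.25 over alternatives), and the adjusted p of the list ran from 0.00286 to 0.575 over the alternatives. The call was also lost without chromosomes 1, 6 and 8 (adjusted p = 0.231), with library size only (0.0681) and without mutant replicate 3 (0.0545).

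Of 24 endoplasmic reticulum chaperone and folding genes, 8 fell and 4 rose. The median was 0.01 and the mean −0.00 (camera adjusted p = 0.807), and the median was −0.05 with library size only and −0.07 with the GC correction and without chromosomes 1, 6 and 8; it also turned negative without wild type replicate 2 (−0.02) or 3 (−0.03) or mutant replicate 2 (−0.01). All 3 members on chromosome 8 or between 40 and 95 Mb of chromosome 6 rose, among them the disulfide isomerase gene Pdia4 (0.77) and the calcium-binding chaperone gene Calr (0.67), and 8 of the other 21 fell. After the GC correction 7 of the 24 were higher and 5 lower. Of 12 mitochondrial chaperone and protease genes, 4 rose and 1 fell (median 0.03, −0.04 with library size only and 0.07 with the GC correction; camera adjusted p = 0.668). Htra2, a protease gene of the chromosome 6 segment, rose by 1.21, and Yme1l1, an inner membrane protease gene, fell by 0.95 (−0.34 with the GC correction). After the GC correction, 1 of the 12 was higher and 1 lower, and without wild type replicate 2 or mutant replicate 2, 2 were higher. Of 15 autophagy genes, 8 fell and 3 rose (median −0.23, camera adjusted p = 0.373). With the GC correction the median was −0.12, with 7 lower and 4 higher. Atg12, a conjugating protein of autophagosome formation, fell by 0.70, and Map1lc3b, the gene of an autophagosome membrane protein on chromosome 8, rose by 0.45. For these 3 lists the counts adjusted over the list alone were the same.

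Of 17 p53 targets, 6 rose and 6 fell (median −0.15, and 0.03 with the GC correction; camera adjusted p = 0.373). Trp53inp1 fell by 1.11 and the cyclin gene Ccng1 by 0.58. Both transcripts are poor in GC (38.8% and 40.8%). After the GC correction Trp53inp1 stood at −0.53 and Ccng1 at −0.12, the latter no longer past the threshold (adjusted p = 0.0541, range over alternatives 1.17e-18 to 0.0592). Of 12 heat shock genes, 4 fell and 3 rose (median −0.06, −0.13 with library size only and 0.15 with the GC correction; camera adjusted p = 0.613). Hsp90aa1, the inducible cytosolic HSP90 gene, fell from 461 ± 24.1 to 226 ± 18.5 CPM (log2 fold change −1.03, SE 0.06, adjusted p = 4.76e-15), and the cochaperone gene Dnajb1, on chromosome 8, rose by 0.71. Adjusted over the list alone, the counts of both lists were the same.

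Among metabolic lists, 11 of 20 cholesterol synthesis genes fell and 2 rose (median −0.21, camera adjusted p = 0.124, with the same counts adjusted over the list alone). Hmgcs1, the HMG-CoA synthase gene, fell by 0.55 (−0.24 with the GC correction), and Insig1, a regulator of sterol synthesis, fell by 0.50. With the GC correction and without chromosomes 1, 6 and 8, the list passed the threshold (adjusted p = 0.0195, range over alternatives 0.0195 to 0.575), which was lost together with an estimated correlation (adjusted p = 0.483). Of 19 glycolysis and hypoxia genes, 8 rose and 5 fell, also adjusted over the list alone (median 0.10, camera adjusted p = 0.302). Hk2, a hexokinase gene of the chromosome 6 segment, rose from 95.7 ± 3.03 to 256 ± 5.39 CPM (log2 fold change 1.42, SE 0.06, adjusted p = 3.99e-19), and the phosphofructokinase gene Pfkp fell by 0.59. The GC correction left 5 members higher and 7 lower, with a median of 0.00, and without chromosomes 1, 6 and 8 as well the median was −0.08. Of 34 subunits of mitochondrial complex I, 6 fell and 4 rose (4 and 4 adjusted over the list alone). Ndufa13 and Ndufb7, both on chromosome 8, rose by 0.67 (0.42 with the GC correction) and 0.60. The list median was −0.03 while camera pointed up (adjusted p = 0.999); with library size only, the replicate block or the GC correction, camera pointed down, and with the GC correction 14 members were lower and 7 higher (median −0.15).

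Markers of the naive pluripotent state were lower on balance but not uniformly. Of 22 tested members, 9 fell and 4 rose, with the same counts adjusted over the list alone (2 higher without mutant replicate 1). The transcription factor gene Tbx3 fell from 186 ± 14.8 to 92.7 ± 5.41 CPM (log2 fold change −1.001, SE 0.06, adjusted p = 2.32e-14). Tfcp2l1, another transcription factor of naive cells, fell from 732 ± 73.3 to 377 ± 6.04 CPM and lies beyond 55 Mb on chromosome 1. Klf4, Nanog and Sox2 fell by 0.51, 0.48 and 0.49 (named after their values were seen), whereas Dppa3 rose from 2.43 ± 0.0730 to 9.54 ± 0.401 CPM. Pou5f1, which encodes the core pluripotency factor OCT4, had 765 ± 54.8 CPM in wild type and 786 ± 66.8 in the mutant (log2 fold change 0.04, adjusted p = 0.622), and Sall4 had −0.05 (adjusted p = 0.435). Both were lower with the GC correction, Pou5f1 at −0.16 (adjusted p = 0.00772, range over alternatives 0.00772 to 0.990) and Sall4 at −0.20 (adjusted p = 0.00104, range 0.00104 to 0.757).

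The naive pluripotency list had a median of −0.06 and did not pass (camera adjusted p = 0.0585, range over alternatives 0.00178 to 0.575). It passed without wild type replicate 1 (0.0337), without wild type replicate 3 (0.0363), with no filter on low counts (0.0286), with the GC correction and without chromosomes 1, 6 and 8 (0.00618), and with the GC correction alone (0.00178), under which 16 members were lower and 4 higher and the median was −0.22. It did not pass with an estimated correlation (adjusted p = 0.483), nor with the GC correction as well (adjusted p = 0.575). Of 16 formative and primed epiblast genes, 9 rose and 4 fell, also adjusted over the list alone (median 0.20, camera adjusted p = 0.233). Sall2 rose by 1.30 and the de novo DNA methyltransferase gene Dnmt3b by 0.74, while Lef1 and Otx2 fell by 0.88 and 0.60 (both named after their values were seen). The GC correction left 5 higher and 4 lower, with a median of 0.08.

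Markers of other cell types were higher in part, mostly from low levels. Of 11 primitive streak and mesoderm genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.45, and 0.19 with the GC correction and without chromosomes 1, 6 and 8; camera adjusted p = 0.124). Evx1, a homeobox gene beside the Hoxa cluster, rose by 1.59 and the growth factor gene Bmp4 by 0.84. Of 16 endoderm genes, 7 rose (4 without wild type replicate 3) and 2 fell (median 0.21, camera adjusted p = 0.124), led by the basement membrane collagen genes Col4a2 (1.04) and Col4a1 (0.91). Those lie head to head on chromosome 8, and with the GC correction 3 members of the list were higher and 3 lower. The list median was then 0.07, and 0.02 without chromosomes 1, 6 and 8 as well. Of 9 neural ectoderm genes, 5 rose and 2 fell (median 0.28, camera adjusted p = 0.0715, range over alternatives 3.53e-04 to 0.575). The median was 0.63 without chromosomes 1, 6 and 8 and 0.09 at a minimum of 1 CPM in 3 libraries. Nes, the gene of the intermediate filament nestin, rose from 37.8 ± 0.562 to 75.3 ± 3.51 CPM (log2 fold change 0.99, SE 0.07, adjusted p = 1.10e-13), and the neural transcription factor gene Sox1, on chromosome 8, rose by 1.74. The neural list passed without wild type replicate 3 (adjusted p = 0.0373), without chromosomes 1, 6 and 8 (0.0369), with the GC correction (0.0206) and with both (3.53e-04). It did not pass with an estimated correlation (adjusted p = 0.483, and adjusted p = 0.575 with the GC correction as well). Except for mesoderm, the counts adjusted over the list alone were the same.

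Of 10 trophectoderm genes, 5 rose and 3 fell, the latter 1 without wild type replicate 3 or mutant replicate 1 (median 0.28, camera pointing up with adjusted p = 0.756, and down with the GC correction, which left 2 higher and 3 lower, with a median of 0.12). Tfap2c, a transcription factor of trophoblast and germ cells, fell by 0.93, and the keratin gene Krt8 rose by 0.38 (0.18 with the GC correction). Of 11 fibroblast genes, markers of cells that can serve as feeders, 8 rose and 2 fell (median 0.52, camera adjusted p = 0.0585, range over alternatives 0.0101 to 0.611). Tagln, an actin-binding protein gene, rose by 0.64 and the collagen gene Col3a1 by 1.30, the latter from 4.40 ± 0.861 to 10.9 ± 1.70 CPM. The fibroblast list passed without wild type replicate 3 (adjusted p = 0.0373), without mutant replicate 3 (0.0215), with the replicate block (0.0464), without chromosomes 1, 6 and 8 (0.0269) and with the GC correction as well (0.0101). It did not pass with an estimated correlation (adjusted p = 0.483, and adjusted p = 0.611 with the GC correction as well). Counts adjusted over the list alone were the same for both lists. Of 10 genes of 2-cell-like cells, a rare state of mESC cultures, 2 fell and 0 rose by edgeR (1 and 0 adjusted over the list alone; 4 and 1 at an unadjusted p under 0.05; 1 and 0 by DESeq2; 2 and 0 by limma voom; median −0.40, camera adjusted p = 0.545). With the GC correction, 3 were lower and 1 higher. Zscan4d fell by 1.10 (−0.75 with the GC correction) and Usp17le by 0.47. Zscan4a, annotated as a pseudogene, and Tmem92, both named after their values were seen, did not pass (0.56, adjusted p = 0.0808; −0.77, adjusted p = 0.0507) but did with the GC correction (0.92, adjusted p = 0.00295; −0.85, adjusted p = 0.0288). Usp17le (adjusted p = 0.0310) was no longer called without wild type replicate 1 (0.0570) or 3 (0.185), without mutant replicate 1 (0.0519) or 2 (0.0844) and with DESeq2 (0.0959), over a range of 0.0108 to 0.185. Zscan4d and Usp17le have near-identical copies.

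Of 19 imprinted genes, 9 rose and 5 fell (9 and 6 adjusted over the list alone). Besides Meg3, Rian and Mirg, the growth factor gene Igf2 rose by 1.20 and its neighbour H19, a noncoding RNA, fell by 1.21, both named after their values were seen. Its median was 0.04 and its mean −0.84; the median was −0.03 with library size only, 0.10 with the GC correction and −0.15 with the GC correction and without chromosomes 1, 6 and 8. Camera called the list lower (adjusted p = 1.91e-04, range over alternatives 2.44e-11 to 0.279). It did not pass with an estimated correlation (adjusted p = 0.279), but passed with that, the GC correction and chromosomes 1, 6 and 8 left out (adjusted p = 0.0376). The call as lower rested on Meg3, Rian and Mirg: the other 16 members had a mean of 0.14, with 9 higher and 2 lower, and camera without the 3 pointed up and did not pass (adjusted p = 0.172). Of 4 Y-linked genes, too few for camera, 2 fell and 1 rose, also adjusted over the list alone, with a median of −0.18. After the GC correction the median was 0.47, with 3 higher and 0 lower by edgeR (also 3 and 0 at an unadjusted p under 0.05; no other tool was run with the correction). Uba1y rose by 0.61. Ddx3y fell by 0.54 (adjusted p = 0.00303) but stood at 0.14 with the GC correction (adjusted p = 0.457, range over alternatives 0.00240 to 0.468); its GC content is 36.1%. Of 18 replication-dependent histone genes, whose mRNAs lack a poly(A) tail, 4 rose and 1 fell, also adjusted over the list alone (median 0.07, camera adjusted p = 0.545). The GC correction left 3 higher and 4 lower, with a median of −0.05; 8 were higher without wild type replicate 1 and 3 lower without mutant replicate 3. Hist1h4d rose by 0.31 and Hist1h4b by 0.34, the latter not past the threshold with the GC correction (0.10, adjusted p = 0.116, range over alternatives 8.63e-09 to 0.126).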

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

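The GC correction, leaving out chromosomes 1, 6 and 8, both together, and leaving Meg3, Rian and Mirg out of the imprinted list were tests chosen after the results were seen; the other alternatives were planned. Of 61 values for the 2 counts of genes and for Atf4 under the alternatives, 57 kept their direction and stayed past the threshold or within 1.5 times the count. The exceptions were the number of genes higher with library size only (1854), with the GC correction and without chromosomes 1, 6 and 8 (2009), and both counts at a fold change of at least 2 (323 higher, 536 lower). The last 3 follow in part from their construction, with fewer genes tested or a stricter threshold; for library size only the cause was not tested. Leaving out 1 library gave 2795 to 3290 genes higher and 3053 to 3617 lower. Of 432 values for the lists, 407 kept their call, 5 lost it, 19 gained it and 1 turned: the imprinted list without Meg3, Rian and Mirg had a median of 0.21, pointed up and was not called. The number of higher members fell by over 1.5 times in 11 of 24 lists with library size only, 6 with the GC correction, 14 without chromosomes 1, 6 and 8 and 12 with both. With the GC correction, the number of higher members rose by over 1.5 times in 3 lists, and that of lower members rose so in 3 and fell so in 1. Without chromosomes 1, 6 and 8, the number of lower members fell by that much in 4 lists, and also in 4 with the GC correction as well. Leaving out 1 library changed the higher count by that much in 0 to 2 lists and the lower count in 0 to 4. The median of the amino acid synthesis list was −0.24 with the GC correction and −0.45 with chromosomes 1, 6 and 8 also left out, past the threshold in both, and that of the aminoacyl-tRNA synthetases −0.32 without those chromosomes and −0.35 with the GC correction as well. With an estimated correlation the synthesis list did not pass (adjusted p = 0.457 with the GC correction, 0.150 with the chromosomes also left out), nor did the synthetases (0.338 with both). Of 1341 values for named genes, 1323 kept their call, 12 lost it, 2 gained it and 4 changed sign. The sign changes were Pou5f1 (−0.16 with the GC correction and −0.16 with the chromosomes also left out) and Ddx3y (0.14 and 0.14). By construction the correction lowers transcripts rich in GC, such as Pou5f1 (57.6%), and raises poor ones, such as Ddx3y (36.1%). The replicate number as a block gave 3087 genes higher and 3338 lower. Libraries with the same number did not deviate together (r of −0.14, −0.05 and 0.02 for numbers 1, 2 and 3). This gave no sign that the numbers pair the samples. The highest r, 0.16, joined wild type replicate 1 and mutant replicate 2, the libraries with the most Rn45s (36.9% each). A weaker shared effect could lie beneath such differences, so pairing is not excluded. Under the block the fibroblast list passed (camera adjusted p = 0.0464, range over alternatives 0.0101 to 0.611, the highest being the adjusted p with the GC correction and an estimated correlation) and no other list or named gene changed its call. Genes below the filter on low counts, among them Slc7a11, could not be judged at this depth.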

Other observations

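Of the tests below, those of GC content and copy number for chromosome 8, the ATF4 programme and Meg3, and that of the genes on the distal side of Meg3, were chosen only after the result was seen, while the tests of the genes on both sides of Meg3, of the HoxA genes and of other splits of the libraries were set before theirs. Hoxa2, Hoxa3, Hoxa7, Hoxa10, 6430411K18Rik, Dio3, Ppp2r5c and Dync1h1 were named after their values were seen. Genes of the HoxA cluster rose together. All 6 tested members (Hoxa1, Hoxa2, Hoxa3, Hoxa5, Hoxa7 and Hoxa10) were higher in the mutant, with a median log2 fold change of 1.92. The filter on low counts can keep a gene through the group where it is higher, which favours genes with a change. Hoxa5, for example, held 21 counts over the wild-type libraries and 97 over the mutant libraries. Of 7 tested genes of the HoxB, HoxC and HoxD clusters, 2 were higher and 0 lower by edgeR (also 0 lower at an unadjusted p under 0.05, by DESeq2 and by limma voom), with a median of 0.56. With the GC correction, 1 was higher and 0 lower, with a median of 0.40. The HoxA genes lie in the segment of chromosome 6 where most genes were higher, and a higher dosage of that segment alone is a candidate explanation. The tested HoxA genes stood 1.04 (95% interval 0.71 to 2.32, 6 genes) above the other genes of the segment after the GC correction. That excess cannot settle whether dosage is the whole cause. The filter favours genes with a change, as given above, and the interval treats these neighbouring genes as independent. Hoxa1 and Hoxa5 were also named for being among the 8 largest rises. Antisense transcripts of the cluster stay open as a source of part of the counts, because the strand setting is not given.

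The 313 tested genes with Zfp symbols, most of them zinc finger proteins, had a median log2 fold change of −0.21 (95% interval −0.32 to −0.17), with 135 lower and 59 higher. This set was not among the 26 gene lists fixed in advance, and its camera p-values are not adjusted. With the GC correction the median was −0.11 (−0.17 to −0.01), with 101 lower and 52 higher, and the comparison with other genes gave a camera p of 0.140, against 0.00164 before it. Their median GC content was 45.3%, against 50.2% over all tested genes.

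Genes of chromosome 8 were higher in all 3 mutant libraries by nearly the same amount. A GC trend between the libraries does not account for it, since the median relative to the other autosomes was 0.54 after the GC correction. Loss of 1 of 2 copies in all wild-type cells would give a median near 1, and the upper bound of the interval was 0.578. A candidate explanation is 3 copies in the mutant cells against 2 in the wild-type cells, a gain known from mESC cultures. The ratio of 3 to 2 copies is 0.585 on the log2 scale, slightly above the upper bound of 0.578. All 15 windows of 5 Mb with at least 20 genes lay above 0.3, a bound chosen after the values were seen. No DNA was analysed here, and because the genotype and the origin of the cells coincide, these libraries do not show whether such a gain belongs to the edited clone, the culture or the mutation.

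The ATF4 programme was lower on balance, with 29 of 65 tested members of the 4 lists lower and 14 higher (median −0.12, 95% interval −0.29 to 0.0012, which reaches above 0). Over all 13101 tested genes, 3493 were lower and 3286 higher. The GC trend does not account for it, since the median after the correction was −0.15 (−0.35 to −0.03). Dosage of the members that themselves lie on chromosomes 1, 6 and 8 does not account for it either. Over the 48 members elsewhere the median was −0.23 (−0.42 to −0.05) without the GC correction. With it, the median was −0.32 (−0.44 to −0.10), and 26 were lower and 5 higher. Leaving out members cannot show whether the shifted chromosomes changed the members elsewhere, because that shift coincides with the genotype. Lower ATF4 output in the mutant may be a cause, in line with the lower Atf4 mRNA, but outside these chromosomes the transporters had the highest of the 4 list medians, 0.02 before the GC correction and −0.10 (−1.001 to 0.15, 9 genes) after it, so whether it is the whole cause stays open. Differences between clones are confounded with the genotype, and with an estimated correlation camera called no ATF4 list. Fry called the synthesis, synthetase and stress lists lower (adjusted p = 0.00243, 0.0119 and 0.0285) but not the transporters (0.871). Lists outside the programme passed fry too, such as the p53 targets as lower and the formative epiblast genes as higher (adjusted p = 0.00243 each).

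Meg3, Rian and Mirg were nearly silent in the mutant, as were all 18 tested symbols from the start of Meg3 to the end of Mirg (109541001 to 109749460 on chromosome 12), most of them microRNAs and snoRNAs. Several of the microRNA symbols lie within Mirg and the snoRNA symbols within Rian. Their reads cannot be told apart from those of the longer RNAs. 6430411K18Rik, a protein-coding entry on the minus strand, fell by 5.48 on the log2 scale. A microRNA symbol on the plus strand lies within it, and the strand setting is not given. Its counts may therefore include antisense reads, so its fall does not show which strand was lost. Loss of the region with the genes on both sides is argued against by the 14 tested genes within 1 Mb, whose median was 0.030 (95% interval −0.28 to 0.24), and by the 8 proximal genes. The median of the proximal genes was 0.15 (−0.04 to 0.29), and 0.006 with the GC correction. Loss reaching beyond the distal end stays open: the 6 distal genes had a median of −0.32 (−1.13 to 0.21), with Dio3, the nearest, at −1.23, Ppp2r5c at −0.47 and Hsp90aa1 at −1.03, but Dync1h1 at 0.39. The GC trend is argued against by the smallest fall of the 3 genes after the correction, −4.97. Loss of 1 of 2 expressed copies is argued against by their smallest fall before it, −5.66. That value does not bear on loss of the maternal copy where only the maternal copy is expressed. A candidate explanation is silencing of the maternal copy or a smaller deletion, neither of which was tested; the labels do not say how many clones were used, so the change may also mark the clone rather than the mutation.

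The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3286 genes higher and 3493 lower, 1 split of the 10 in each case, and the highest other split gave 0 by edgeR (at most 245 genes at an unadjusted p under 0.05, against 7434 for the real split; no other tool was run on the splits). Every other split puts libraries of both genotypes in each group. The difference between genotypes then adds to the spread within the groups and lowers the number of calls. The 0 is thus not a measure of what chance gives. For the number of lists called by camera, the real split gave 2, the highest other split gave 4, and 6 of the 10 splits gave as many as the real one.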
